A study of Macaca mulatta with 19 samples.

How the data were processed

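RNA was measured in luteinized granulosa cells aspirated from the naturally selected periovulatory follicle of rhesus macaques, per the labels. The animals carried implants with cholesterol (C) or testosterone (T, 4 to 5 fold above C) and ate chow or a Western-style diet (WSD) for about 3.5 years, in a factorial design with 10 animals enrolled per treatment and 7 to 10 in controlled ovulation cycles. Per the labels' protocols, RNA was purified with the Promega ReliaPrep cell kit and made into polyA-selected, non-directional libraries with the TruSeq v2 kit. No sort or gate of the aspirated cells is named in the labels.

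The deposited values are raw read counts per gene, in 1 table with a column for each of 19 libraries. Reads were trimmed with Trimmomatic and aligned with STAR, per the submitters' processing notes; their versions, the genome build and the annotation are not given in the sources used here. The table holds 32386 genes under Ensembl macaque identifiers and 4 further classes that count ambiguous, multimapping, no-feature and unmapped reads. A symbol stood beside 21539 of these genes, and 1383 more received one from a reference table that pairs gene identifiers with symbols, in which 17621 identifiers were found. No coordinates are given because the build of the counts is unknown. All 19 columns matched a sample's label. Since the libraries carry no strand information, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, among them the alpha globins, are uncertain.

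Gene counts per library ranged from 28832132 to 56385679. Reads carry no molecular identifiers, so the depth sets only the counting error; differences between animals were far larger, with a biological coefficient of variation of 0.583 (common dispersion 0.34). Each library is 1 animal. Replicate numbers were given here in the order of the samples and pair nothing across groups.

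Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15019 genes for the treatment comparisons and 14976 for the oocyte comparisons. Libraries were scaled by TMM, and each comparison was tested two-sided by edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All 19 libraries entered 1 fit of the 4 treatment groups, from which the 5 comparisons between pairs of groups, both main effects and the testosterone by diet interaction were taken. A second fit of 18 libraries compared oocyte classes with the treatment group as a term. Its classes were MI (metaphase I, 8), MII (metaphase II, 4) and degenerating (6), and the 1 library with a GV (germinal vesicle) oocyte was left out because it has no replicate. CPM values in the text are TMM-scaled, except those of mitochondrially encoded genes, which are per gene counts without scaling. They are given with means ± SD over libraries, and fold changes are fitted log2 values with their SE or 95% confidence interval.

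The comparisons, tests, thresholds, gene lists and the rule for naming genes were set before the data were examined. Of the lists, 22 hold genes of pathways: steroid synthesis, cholesterol synthesis and uptake, cholesterol efflux and storage, fatty acid synthesis and lipid storage, fatty acid oxidation, ovulatory response, preovulatory granulosa, androgen response, extracellular matrix and proteases, cytokines and NF-kB, interferon response, oxidative stress defence, endoplasmic reticulum stress, heat shock, cell cycle, apoptosis, hypoxia and glycolysis, oxidative phosphorylation, insulin and IGF signalling, TGF-beta and BMP signalling, angiogenesis, and prostaglandin pathway. The other 12 hold markers of macrophage, lymphocyte, neutrophil, leukocyte, erythroid, platelet, theca and stroma, endothelium, smooth muscle, surface epithelium, oocyte and granulosa cells. Lists with at least 5 tested members, which were all 34, were tested by camera at a preset correlation of 0.01 with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it (limma 3.58.1). A list score is the mean log2 CPM (prior count 1) of a list's tested members in a library; scores were compared between groups by exact permutation tests, two-sided, for each comparison except the interaction, added after the data were seen. Principal components were computed from centred log2 CPM, and 5 relations between scores and the first component were tested with 100000 permutations each.

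The genes named are, per comparison, up to 12 higher and 12 lower genes past the threshold with a symbol and a mean log2 CPM of at least 0. Where fewer than 5 genes passed, those that passed and the 10 with the smallest p were taken instead, and the latter are given as not past the threshold. To these were added list members that passed when adjusted over the list alone (at most 4 per list), and a panel of STAR, CYP11A1, HSD3B2, CYP19A1, LHCGR, FSHR, PGR, ESR2, AMH, INHA, INHBA, PTGS2, AREG and SCARB1; 2 further genes of the panel are not reported here. AMH and INHBA matched no tested gene. The set was shortened in the text where comparisons repeat a gene.

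The gene tests were recomputed with RLE factors in place of TMM, without the low-count filter, and with DESeq2 1.42.0. They were also run with limma voom and sample quality weights, and with the leukocyte score or the oocyte class as a covariate. Further fits used MI and MII libraries only, or only the 2 groups compared. Where oocyte classes were compared, fits without the treatment term or with a 2-level oocyte factor were added. Each library was also left out in turn. List tests were repeated only with the leukocyte score as a covariate, without 1 library and without the 2 libraries of highest leukocyte score. These repeats were chosen after the data were seen. So were fits without the 2 libraries of highest leukocyte score (WSD+C replicate 4 and WSD+T replicate 6) or without these and Chow+C replicate 2. Fits that combine a covariate or a left-out library with no treatment term were too. For each comparison 100 splits of the libraries into groups of the same sizes, the real one included, were refitted.

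The pipeline was tested on simulated data for each comparison. Counts were drawn from the real means and depths with 200 genes changed by known folds. For testosterone vs control on chow (15019 genes), edgeR recovered 19.4% of the genes changed 2 fold, 76.1% of those changed 4 fold and 74.2% of those changed 8 fold, with 8 calls outside the changed genes. For the testosterone by diet interaction (15019 genes) it recovered 10.4%, 50.7% and 66.7%, with 7 calls outside, and for MII vs MI oocyte (14976 genes) 11.9%, 55.2% and 81.8%, with 3. On testosterone vs control on chow DESeq2 called 62 genes outside the changed ones and limma 6. A list shifted 1.5 fold passed camera's preset test in each comparison except the interaction (adjusted p = 0.17). Simulated genes vary independently, which real genes do not. Figures were drawn with matplotlib 3.10.9.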

Results

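Luteinized granulosa cells were profiled by RNA sequencing in 19 rhesus macaques, 1 library per animal. The series asks what chronic testosterone, a Western-style diet (WSD) or both do to granulosa cells and to the quality of the oocyte in the same follicle. The groups were Chow+C (chow and a cholesterol implant, the control, n = 4), Chow+T (chow and testosterone, n = 4), WSD+C (n = 5) and WSD+T (n = 6). By the oocyte class in the labels, 8 libraries came with an MI (metaphase I) oocyte, 4 with an MII (metaphase II) oocyte, 6 with a degenerating oocyte and 1 with a GV (germinal vesicle) oocyte. Chow+C held 3 MI and 1 MII, Chow+T 2 MII, 1 degenerating and 1 GV, WSD+C 3 MI and 2 degenerating, and WSD+T 2 MI, 1 MII and 3 degenerating. Libraries are written below as the group and the replicate number, so that Chow+C 2 is replicate 2 of Chow+C.

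Gene counts in Chow+C 1 to 4 were 35233042, 28832132, 35197029 and 43250060. Those in Chow+T 1 to 4 were 54804607, 39070550, 41944863 and 43306781. WSD+C 1 to 5 held 41175908, 39427622, 45280532, 35338126 and 40433333. WSD+T 1 to 6 held 35582942, 42298306, 53309167, 56385679, 39946249 and 38318351. In Chow+C 2 only 49.1% of reads fell in genes, against 55.9% to 69.1% in the others, and its mitochondrial genes took 17.9% of gene counts. Log2 counts of any 2 libraries correlated at 0.912 to 0.991.

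Granulosa marker genes were present in all libraries. The granulosa marker score was 7.15 ± 0.56 (SD, n = 19, mean log2 CPM), and 10 of its 11 members, all but LHCGR, were at 1 CPM or more in every library. The leukocyte score (CD53, CORO1A, PTPRC and 9 other genes of white blood cells) was 2.55 ± 2.16 and ranged from -0.49 in WSD+C 1 to 7.5 in WSD+T 6. Of the marker genes for cells other than granulosa, 3 of 12 for leukocytes, 2 of 14 for macrophages, 1 of 13 for lymphocytes, 0 of 11 for neutrophils, 3 of 9 for erythroid cells, 1 of 6 for platelets, 6 of 10 for theca and stroma, 2 of 8 for endothelium, 4 of 8 for smooth muscle and 1 of 9 for oocytes reached 1 CPM in every library. WSD+C 4 stood apart, with HBB at 96410 CPM, ACTA2 at 1942 CPM and STAR at 225 CPM. Its erythroid score was 8.87, its oocyte score 4.43 and its granulosa score 5.6.

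**Figure D1:**
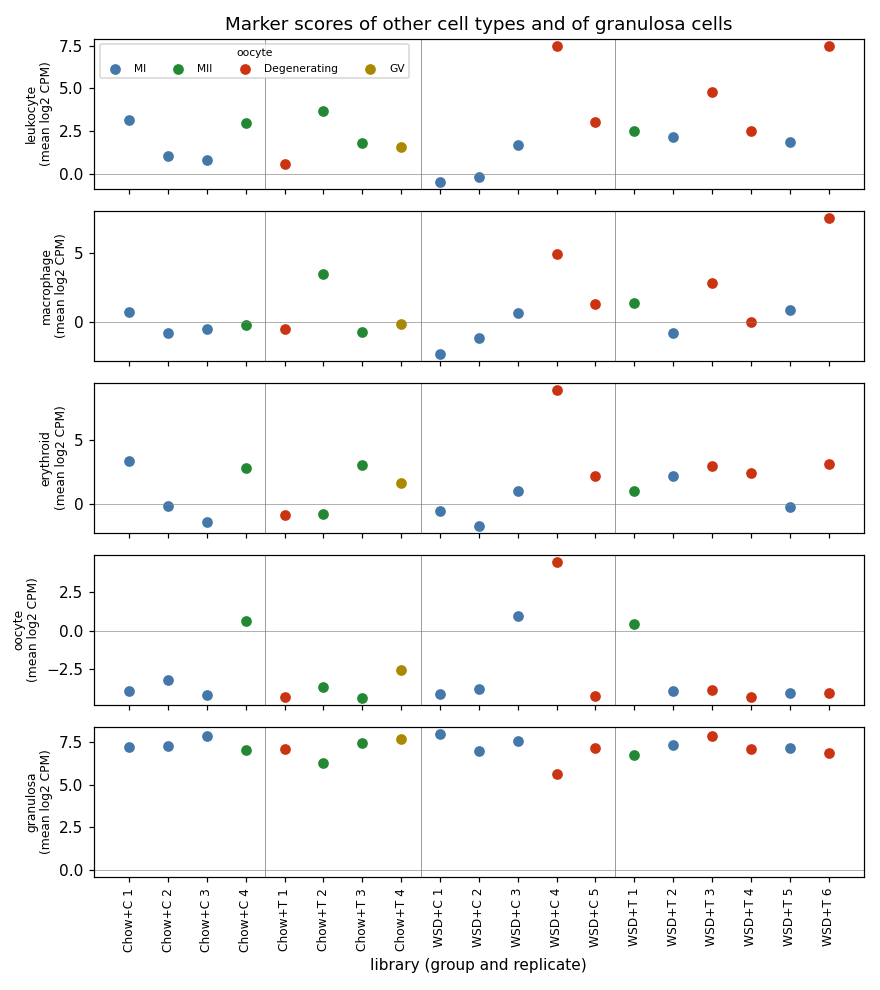
Leukocyte, macrophage, erythroid, oocyte and granulosa marker scores (y axes, mean log2 CPM of a list's genes) of the 19 libraries (points, coloured by oocyte class), set out along the x axis by treatment group. The leukocyte score reached 7.46 in WSD+C 4 and 7.5 in WSD+T 6.

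The first principal component held 34.4% of the variance and followed the leukocyte score. Over the 19 libraries Pearson's r was 0.925 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 5e-05) and Spearman's rho 0.851 (permutation p = 2e-05, adjusted p = 1e-04). Without WSD+T 6 and WSD+C 4, the libraries farthest from the median score, r was 0.839. Treatment groups accounted for 6.21% of this component and the leukocyte score for 85.7%. After subtracting group means r was 0.944, and within WSD+T (n = 6) it was 0.989. Of the other 4 relations in the family of 5, the leukocyte and erythroid scores gave r = 0.778 (permutation p = 4e-05, adjusted p = 1e-04), rho = 0.732 (permutation p = 4.3e-04, adjusted p = 0.0011) and r = 0.61 without WSD+C 4 and WSD+C 2. The component's relation with the erythroid score (r = 0.767, permutation p = 4.4e-04, adjusted p = 7.3e-04; rho = 0.563, permutation p = 0.013, adjusted p = 0.022) was r = 0.426 without the same 2. Its relation with the granulosa score (r = -0.60, permutation p = 0.013, adjusted p = 0.013; rho = -0.425, permutation p = 0.071, adjusted p = 0.071) was r = -0.167 without WSD+C 4 and Chow+T 2 and rested on them. The leukocyte and granulosa scores (r = -0.58, permutation p = 0.011, adjusted p = 0.013; rho = -0.463, permutation p = 0.048, adjusted p = 0.06) gave r = -0.295 without those 2. All tests were two-sided, and the labels give no batch. Components 2, 3 and 4 held 12.2%, 9.02% and 6.46% of the variance. Treatment groups accounted for 10%, 34.4% and 18.8% of them, which was not tested.

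**Figure D2:**
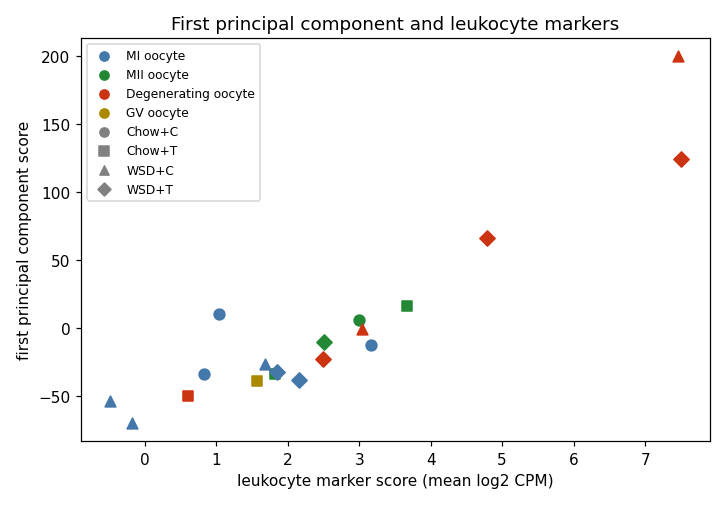
First principal component score (y axis, no unit) against the leukocyte score (x axis, mean log2 CPM) for the 19 libraries (points), coloured by oocyte class and shaped by treatment group. Pearson's r was 0.925, and 0.839 without WSD+T 6 and WSD+C 4.

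Testosterone was first compared with control on chow. SDC4 (ENSMMUG00000048424), a cell-surface heparan sulfate proteoglycan, averaged 16.2 ± 2.31 CPM (SD, n = 4) in Chow+C and 45.4 ± 15.7 CPM (n = 4) in Chow+T, a fitted log2 fold change of 1.48 (SE 0.263). FHL2 (ENSMMUG00000016594), a LIM-domain protein, averaged 29.7 ± 16.8 and 93.7 ± 21.6 CPM (log2 fold change 1.66, SE 0.356), and MLF1 (ENSMMUG00000004958) 3.94 ± 2.30 and 22.4 ± 12.53 CPM (2.51, SE 0.5). Among the 10 genes of smallest p were also the translation release factor ETF1 (0.92), the transcription regulator ARID5B (1.45), NUFIP2 (0.94), ZNF212 (-0.66), ZNF23 (-0.64), the mitochondrial topoisomerase TOP1MT (-1.27) and ENSMMUG00000041107 (-2.83, and -1.74 without Chow+C 2). The steroidogenic genes STAR (95% CI -2.05 to 1.08), CYP11A1 (CI -1.73 to 1.15) and CYP19A1 (CI -1.99 to 1.43) had intervals on both sides of 0.

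With testosterone on chow, 0 of 15019 genes passed edgeR's test (smallest adjusted p = 0.388). At an unadjusted p under 0.05 there were 1079 genes (348 higher, 731 lower), where chance gives 751. Leaving out 1 library, that number ranged from 495 (without Chow+T 3) to 1744 (without Chow+C 4), and was 532 without Chow+C 2. Limma called 0 and DESeq2 5, namely SDC4 (adjusted p = 7.19e-04), MLF1 (9.07e-04), FHL2 (0.0182), ZNF212 (0.0267) and FCRL1 (6.94e-19), a gene outside the naming rule and chosen after its values were seen. FCRL1 had a fitted log2 fold change of -21.45 by DESeq2, with 0 counts in all 4 Chow+T libraries, 0 to 43 in Chow+C and 359 (8.47 CPM) in WSD+C 4, and edgeR gave -7.09 (SE 2.83). With the MI and MII libraries alone edgeR called 4, SDC4 (log2 fold change 1.78, adjusted p = 0.029) with NOCT, FAM53C and JMJD1C. The last 3 were also chosen after their values were seen. That fit held 2 Chow+T libraries, both MII, against 3 MI and 1 MII in Chow+C. Oocyte class thus differed between the groups along with testosterone. Oxidative phosphorylation genes, all nuclear here, rose by camera (median log2 fold change 0.22, 21 of 23 positive, adjusted p = 0.0087), and lymphocyte markers fell (median -1.78, 0 of 13 positive, adjusted p = 0.0335). Both had an adjusted p = 0.886 with an estimated correlation. The first call was lost without Chow+C 2 (0.07) or Chow+T 4 (0.12). The second was lost without any 1 of Chow+C 1 or 4, Chow+T 1, 2 or 4 or WSD+T 3 or 6 (medians -1.92 to -1.25). The androgen response list had a median of 0.19 with 12 of 20 positive (camera adjusted p = 0.293). No member of a list passed when adjusted over the list alone.

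The Western-style diet without testosterone was compared with chow. LIMS1 (ENSMMUG00000009156), an adaptor of integrin signalling, averaged 73.1 ± 15.2 CPM (n = 4) in Chow+C and 134 ± 35.0 CPM (n = 5) in WSD+C, a log2 fold change of 0.88 (SE 0.185). FHL2 averaged 75.9 ± 24.6 CPM in WSD+C (1.35, SE 0.34). Further genes of small p were C10orf11 (2.12), SH2D7 (-2.75, and -1.21 without Chow+C 2), KCTD17 (-0.65), VPS9D1 (-0.86), the hydroxylase KDM8 (-0.73), the RNase MRP RNA ENSMMUG00000038988 (5.15, and 3.57 without WSD+C 1, where it was highest at 4.66 CPM), and ENSMMUG00000047461 (3.35) and ENSMMUG00000039486 (2.65). FSHR, the follicle-stimulating hormone receptor, was at 5.69 ± 2.00 CPM in Chow+C and 20.5 ± 33.9 CPM in WSD+C (1.85, CI 0.17 to 3.52); without WSD+C 4 its log2 fold change was -0.10.

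For diet without testosterone edgeR called 0 of 15019 genes (smallest adjusted p = 0.83), as did DESeq2 and limma. There were 763 genes at an unadjusted p under 0.05 (375 higher, 388 lower). The surface epithelium marker MSLN passed when adjusted over the list alone (fitted 5.78, SE 1.79; 1.46 without WSD+C 4), with means of 0.0602 CPM in Chow+C and 3.49 ± 7.41 CPM in WSD+C. Macrophage markers rose by camera (median 2.92, 14 of 14 positive, adjusted p = 0.0319), as did oxidative phosphorylation genes (median 0.18, 22 of 23 positive, adjusted p = 0.0158). Each had an adjusted p = 0.829 with an estimated correlation. The macrophage median was 0.06 without WSD+C 4 and 0.35 with the leukocyte score as a covariate, the call lost in both, and the call was also lost without Chow+C 3 (2.58), Chow+C 4 (3.27) or WSD+C 5 (3.13). The oxidative phosphorylation call was lost without Chow+C 2 (0.02), WSD+C 1 (0.11) or WSD+C 2 (0.09), and its median was 0.30 without WSD+C 4.

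Both exposures together (WSD+T) were compared with control (Chow+C); this comparison and the 2 before it share the same 4 control libraries. Camera at its preset correlation called 9 lists higher, none of which passed with an estimated correlation. All 23 oxidative phosphorylation genes had positive log2 fold changes (median 0.33), as did 16 of 18 genes of fatty acid oxidation (median 0.46), which feeds the respiratory chain. Genes of cholesterol efflux and storage (median 0.62, 14 of 16 positive), oxidative stress defence (0.36, 16 of 18) and the prostaglandin pathway (0.47, 13 of 16), which acts in ovulation, had positive medians as well. FHL2 averaged 100.6 ± 28.9 CPM (n = 6) against 29.7 ± 16.8 CPM (n = 4; log2 fold change 1.76, SE 0.337), SDC4 34 ± 11.1 against 16.2 ± 2.31 CPM (1.07, SE 0.243) and BBS12 (ENSMMUG00000030171), of the chaperonin-like complex of cilia, 11.1 ± 2.88 against 28.2 ± 13.5 CPM (-1.35, SE 0.305). The lubricin gene PRG4 (-1.76), EFCAB12 (-3.92), MTMR11 (-1.58), DNAAF3 (-2.05), RNF115 (0.53), ENSMMUG00000041107 (-2.56) and ENSMMUG00000041144 (2.92) completed the 10 of smallest p. Without Chow+C 2 EFCAB12 gave -1.80, DNAAF3 -0.72 and ENSMMUG00000041107 -1.47.

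For both exposures edgeR called 0 of 15019 genes (smallest adjusted p = 0.717; 1014 at an unadjusted p under 0.05, 460 higher and 554 lower) and limma 0. DESeq2 called 3, FHL2 (adjusted p = 0.00154), EFCAB12 (0.0252) and ENSMMUG00000041144 (0.0435). Camera's adjusted p was 1.26e-08 for oxidative phosphorylation, 0.00113 for fatty acid oxidation, 0.00134 for efflux and storage and for oxidative stress defence, and 0.00651 for prostaglandins. For these 5 the adjusted p = 0.528 with an estimated correlation. These 5 calls held in all 19 fits that each left out 1 library. Their medians ranged from 0.18 (without Chow+C 2) to 0.43 for oxidative phosphorylation, 0.34 to 0.52 for fatty acid oxidation, 0.27 (without WSD+T 6) to 0.70 for efflux, 0.25 to 0.56 (without Chow+C 1) for oxidative stress and 0.41 to 0.55 for prostaglandins. Efflux was 0.27 without both WSD+C 4 and WSD+T 6 and 0.41 with the leukocyte score as a covariate. Cholesterol synthesis and uptake also rose by camera (median 0.22, 20 of 23 positive, adjusted p = 0.0325; adjusted p = 0.86 with an estimated correlation). That call was lost without Chow+C 2 (0.11), Chow+C 4 (0.06), WSD+T 3 (0.16) or WSD+T 5 (0.24), and its median was 0.34 without Chow+C 3 and 0.54 with the leukocyte score as a covariate.

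White blood cell markers moved with these lists. Macrophage (median 4.31, 14 of 14 positive, camera adjusted p = 3.39e-05), neutrophil (1.58, 11 of 11, 0.00134) and leukocyte markers (3.36, 12 of 12, 0.00206) rose in WSD+T against Chow+C. The first 2 had an adjusted p = 0.528 with an estimated correlation and the last 0.535. Adjusted over the list alone, 12 of 14 macrophage markers passed, against 0 over all genes, led by MRC1 (mean 99.96 CPM in WSD+T, 582 CPM in WSD+T 6 and 0.34 CPM in Chow+C), FCER1G, CD14 and VSIG4. Without WSD+T 6 the macrophage median was 1.37, the leukocyte median 0.86 with its call lost, and the neutrophil median 1.20 with its call lost. With the leukocyte score as a covariate the macrophage median was 0.73 (adjusted p = 0.017 by camera), and the neutrophil call (0.50) was lost. Exact permutation tests of the list scores, two-sided, gave a smallest adjusted p of 0.324, for apoptosis (0.22 higher on the log2 scale), and 0.486 for oxidative phosphorylation (0.35 higher). With 210 arrangements of the libraries a single list could not pass after adjustment.

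Testosterone was compared with control on the Western-style diet to ask what androgen adds to the diet. IL18R1 (ENSMMUG00000009244), a cytokine receptor subunit, averaged 7.27 ± 3.10 CPM (n = 5) in WSD+C and 2.18 ± 0.68 CPM (n = 6) in WSD+T, a log2 fold change of -1.73 (SE 0.419). Other genes of small p were TMEM98 (-1.05), the proline synthesis gene ALDH18A1 (-0.73), ZSCAN12 (-1.51), ADAM18 (-1.53), ACSL6 (-4.07), ITLN1 (-4.25), PGM5 (-3.21), CKB (4.36) and ENSMMUG00000029022 (6.53). ACSL6, ITLN1 and PGM5 had SDs above their means in WSD+C, and without WSD+C 4 they gave -0.14, -0.11 and -1.08, and ZSCAN12 -0.76. ENSMMUG00000029022 was at 190.1 CPM in WSD+T 6 and gave 0.66 without it. Genes of cholesterol synthesis and uptake, the substrate supply for steroids, were higher (median 0.30, 23 of 23 positive, camera adjusted p = 6.06e-08; 0.48 without WSD+C 3, and 0.04 without WSD+C 4, where the call was lost; 0.75 with the leukocyte score as a covariate; adjusted p = 0.561 with an estimated correlation). Cell cycle genes fell (median -0.67, 3 of 25 positive, camera adjusted p = 1.51e-05; adjusted p = 0.561 with an estimated correlation) in all 19 fits that left out 1 library, with medians from -0.92 to -0.34, the last without WSD+C 4.

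For testosterone on the Western-style diet 0 of 15019 genes passed by edgeR (smallest adjusted p = 0.999), DESeq2 or limma, and 579 were at an unadjusted p under 0.05 (105 higher, 474 lower). Camera called 12 lists, each with an adjusted p = 0.561 with an estimated correlation. Besides the 2 above, fatty acid oxidation (0.35), cholesterol efflux and storage (0.38), oxidative phosphorylation (0.15), the ovulatory response (0.19) and steroid synthesis (0.15) rose, with adjusted p from 9.33e-05 to 0.046. Without WSD+C 4 all 5 lost the call, with medians of 0.19, 0.22, 0.02, 0.02 and -0.05. Fatty acid oxidation was 0.19 without WSD+T 3, and without WSD+C 3 the ovulatory response was 0.36 and steroid synthesis 0.25. Efflux also lost its call without WSD+T 6 (0.13), and steroid synthesis without Chow+C 2 (0.15), WSD+T 2 (0.15), WSD+T 3 (0.05) or WSD+T 5 (0.08). Oxidative phosphorylation was 0.26, the ovulatory response 0.49 and steroid synthesis 0.52, each called, with the leukocyte score as a covariate. Preovulatory granulosa genes, among them FSHR, fell (median -0.37, adjusted p = 0.0175), not without WSD+C 1 (-0.13), WSD+C 4 (-0.23), WSD+T 1 (-0.27) or WSD+T 6 (-0.29), nor with the covariate (-0.31). FSHR passed when adjusted over the list alone (-2.29, SE 0.698), and without WSD+C 4 its log2 fold change was -0.35.

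Marker lists were called in the same comparison, all lost with an estimated correlation. Macrophage markers were higher in WSD+T (median 2.26, adjusted p = 0.00106 by camera), but the median was -1.29 without WSD+T 6 and the call was lost there and without WSD+C 1 (1.96); it was 4.68 without WSD+C 4, 1.25 without both of these libraries, and 0.21 with the call lost with the leukocyte score as a covariate. Neutrophil markers were called higher (median 0.12, adjusted p = 3.07e-04), but the median was -0.42 to -0.07, opposite to the test, without any 1 of WSD+C 1, 2, 3 or 5 or WSD+T 3 or 6, 3.28 without WSD+C 4, and 1.34 with the covariate. Erythroid markers were lower (median -4.40, adjusted p = 0.0343), with ALAS2 at 998 ± 2221 CPM in WSD+C and 17.6 ± 14.96 CPM in WSD+T, and 8 of 9 passed when adjusted over the list alone. Without WSD+C 4 the erythroid median was 1.45 with an adjusted p = 0.00161 by camera; the call was also lost without WSD+T 1, 2, 4 or 5 (medians -4.53 to -4.18), and the median was -1.07 with the covariate. Oocyte markers were lower (median -4.11, 0 of 9 positive, adjusted p = 2.92e-04), and ZAR1 and BMP15 passed over the list alone. BMP15, a growth factor secreted by the oocyte, was at 14.4 ± 29.9 CPM in WSD+C, with WSD+C 4 at 67.7 CPM, and 0.0617 ± 0.126 CPM in WSD+T. The call held in the 16 fits that could be made, with medians from -4.45 to -3.67, and with the leukocyte score as a covariate (-1.66); without WSD+C 3, WSD+C 4 or WSD+T 1 too few oocyte markers were left to test.

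The diet was then compared with chow under testosterone. RASSF9 (ENSMMUG00000044627), of the Ras-association domain family, averaged 8.46 ± 2.68 CPM (n = 4) in Chow+T and 2.31 ± 1.12 CPM (n = 6) in WSD+T, a log2 fold change of -1.87 (SE 0.425). The chromatin remodelling gene ARID1B (-0.66), HBP1 (-0.83), the collagen lysyl hydroxylase PLOD2 (-0.67), SKI (-0.59), C5orf41 (-0.93) and SNX16 (-1.37, and -0.59 without Chow+T 3) had negative values, and BLOC1S2 (0.58), ENSMMUG00000012324 (1.62) and ENSMMUG00000049007 (3.16) positive ones. Lymphocyte (median 3.27, 13 of 13 positive) and neutrophil markers (2.73, 11 of 11) were called higher in WSD+T, each with a camera adjusted p = 8.32e-05. With an estimated correlation their adjusted p was 0.693 and 0.691. Both calls held in all 19 fits that left out 1 library, the lymphocyte median being 1.99 without WSD+T 6. Both were lost with the leukocyte score as a covariate, with medians of 0.17 (adjusted p = 0.398 by camera) and 0.52 (0.111). That score also measures white blood cells, so this loss tells little.

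For diet under testosterone edgeR called 0 of 15019 genes (smallest adjusted p = 0.862; 747 at an unadjusted p under 0.05, 331 higher and 416 lower) and limma 0. DESeq2 called 4, RASSF9 (adjusted p = 0.0389), BLOC1S2 (0.0389), ENSMMUG00000049007 (0.018) and FCRL1 (1.59e-21). With the MI and MII libraries alone edgeR called JMJD1C, also chosen after its values were seen. There 2 Chow+T libraries, both MII, met 2 MI and 1 MII in WSD+T, so oocyte class differed along with diet. Leukocyte (median 3.17) and macrophage markers (3.24) rose by camera, each with adjusted p = 0.00351 and an adjusted p = 0.693 with an estimated correlation. Without WSD+T 6 their medians were 0.66 and -0.39 and without Chow+T 1 2.81 and 2.90, where both calls were lost; the macrophage median was 5.49 without Chow+T 2. Cell cycle genes fell (median -0.42, adjusted p = 0.00228; lost without Chow+T 2, -0.23), as did insulin and IGF signalling (-0.22, 4 of 20 positive, 0.00632; lost without WSD+T 1, -0.15). Their adjusted p was 0.693 and 0.66 with an estimated correlation. Cholesterol synthesis and uptake (0.21, 0.0337), endothelium (0.73, 0.0367) and platelet markers (1.36, 0.0367) rose, with an adjusted p of 0.693, 0.691 and 0.691 with an estimated correlation. Cholesterol synthesis lost its call without Chow+C 2 (0.21), Chow+T 2 (-0.03), WSD+T 2 (0.19) or WSD+T 5 (0.18), and was 0.49 without Chow+T 4. Endothelium lost it without Chow+C 2 (0.76), Chow+T 1 (1.09), Chow+T 4 (1.68) or WSD+T 6 (0.24), and platelets without any 1 of Chow+C 2, Chow+T 1, 2 or 4 or WSD+T 2, 3 or 6 (0.29 to 1.59). The leukocyte score as a covariate gave 0.65 for cholesterol synthesis, with its call, and the calls were lost for macrophage (-0.06), endothelium (0.07) and platelet markers (0.06) and for insulin and IGF signalling (-0.19). No member passed when adjusted over the list alone.

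Averaged over both diets, testosterone (n = 10) was compared with cholesterol implants (n = 9). All 23 oxidative phosphorylation genes (median 0.17) and all 16 genes of cholesterol efflux and storage (median 0.45) had positive log2 fold changes, as did 16 of 18 of fatty acid oxidation (0.26). SDC4 gave 0.92 (SE 0.172), MLF1 1.42 (SE 0.319), FHL2 1.03 (SE 0.231) and MAFF (ENSMMUG00000045506), a small bZIP transcription factor, 0.87 (SE 0.203; 62.2 ± 4.41 CPM in Chow+C, 130.4 ± 56.1 in Chow+T, 69.3 ± 6.14 in WSD+C and 111 ± 41.3 in WSD+T). ETF1 (0.60), OTUD1 (1.03), the kinase gene ABL2 (1.31), the sphingosine phosphate receptor S1PR2 (1.19), PCLO (-1.66) and PHF14 (-0.36) completed the 10 of smallest p. For these 10 edgeR's adjusted p was 0.66 or more. FSHR gave -1.05 (CI -2.16 to 0.07), and -0.07 without WSD+C 4.

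For this main effect edgeR called 0 of 15019 genes (smallest adjusted p = 0.66; 948 at an unadjusted p under 0.05, 277 higher and 671 lower) and limma 0. DESeq2 called 3, SDC4 (adjusted p = 0.00303), MLF1 (0.0333) and FCRL1 (2.76e-14). Camera's adjusted p was 1.58e-05 for oxidative phosphorylation, 2.03e-04 for efflux and storage and 0.00177 for fatty acid oxidation, each with an adjusted p = 0.678 with an estimated correlation. All 3 calls held in the 19 fits that left out 1 library, with medians from 0.09 (without Chow+C 2) to 0.22, from 0.20 (without WSD+T 6) to 0.50 and from 0.19 to 0.31. Without both WSD+C 4 and WSD+T 6 fatty acid oxidation lost its call (0.16, adjusted p = 0.0845 by camera), and the other 2 medians were 0.11 and 0.21. Cholesterol synthesis and uptake (0.18, 0.00569) was lost without Chow+C 4 (0.09), WSD+C 4 (0.03) or Chow+T 4 (0.06) and was 0.29 without Chow+T 2, and the ovulatory response (0.16, 0.0126) without Chow+T 1 (0.13) or WSD+C 4 (0.05), with 0.27 without Chow+C 2. Their adjusted p was 0.685 and 0.678 with an estimated correlation. Oxidative stress defence (0.16, 0.0496; 0.678 with an estimated correlation) kept its call in 8 of 19 such fits (0.08 to 0.24); it was lost without Chow+C 2, 3 or 4, Chow+T 1, 3 or 4, WSD+C 4 or 5 or WSD+T 3, 5 or 6. Interferon response genes fell (-0.39, 0.031; 0.685 with an estimated correlation), a call lost without Chow+C 4 (-0.01), WSD+C 4 (-0.06), Chow+T 1 or 4 or WSD+T 1, 4 or 5 (-0.41 to -0.31), with -0.72 without WSD+T 6, and also lost without both WSD+C 4 and WSD+T 6 (-0.24). Cholesterol synthesis was 0.37 and the ovulatory response 0.25, both called, with the leukocyte score as a covariate.

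Marker lists were also called with testosterone, the 5 below each with an adjusted p = 0.678 with an estimated correlation. Oocyte markers were lower (median -3.91, camera adjusted p = 0.00203), and ZAR1, BMP15, GDF9 (-1.03, and -0.48 without WSD+C 4) and NLRP5 passed when adjusted over the list alone, against 0 over all genes; the call was lost without Chow+C 4 (-1.58) and could not be tested without WSD+C 3, WSD+C 4 or WSD+T 1. GDF9, a growth factor of the oocyte, averaged 4.41 ± 3.07 CPM in Chow+C, 2.62 ± 0.58 in Chow+T, 6.94 ± 8.28 in WSD+C and 2.80 ± 0.85 in WSD+T. Macrophage markers were higher (1.74, 0.00177; 0.94 without Chow+T 2 and 0.08 without WSD+T 6, the call lost in both, and 2.97 without WSD+C 4). Lymphocyte (-2.60, 0.00626), smooth muscle (-1.26, 0.031) and erythroid markers (-2.70, 0.0426) were lower. Without WSD+C 4 these 3 medians were 0.00, -0.11 and 0.40. Their calls were also lost without Chow+C 1 or 4 or Chow+T 1 or 2 (lymphocyte -2.48 to -2.32, smooth muscle -1.31 to -1.11, erythroid -2.68 to -2.42), smooth muscle and erythroid without WSD+T 1 (-1.19 and -2.62), and erythroid without Chow+T 4 or WSD+T 5 (-2.62 and -2.60). Medians with the leukocyte score as a covariate were -2.21 for oocyte, 0.44 for macrophage, -1.18 for lymphocyte, -0.79 for smooth muscle and -0.27 for erythroid markers, the last without a call.

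**Figure D3:**
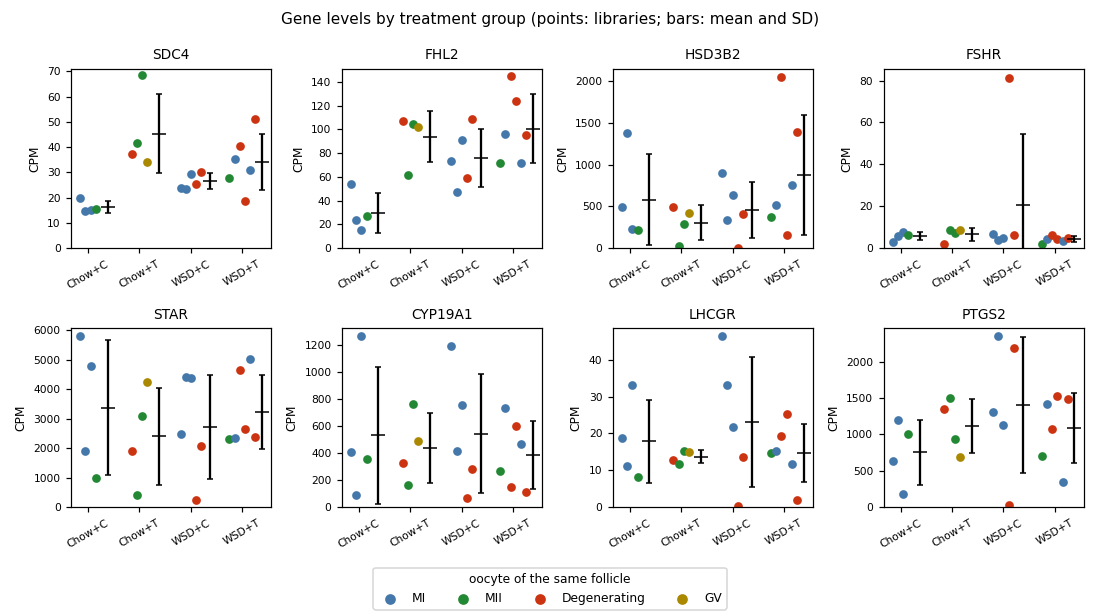
CPM (y axis) of SDC4, FHL2, HSD3B2, FSHR, STAR, CYP19A1, LHCGR and PTGS2 in the 4 treatment groups (x axis), with a point per library coloured by oocyte class and bars for the mean and SD. SDC4 averaged 16.2 CPM in Chow+C and 45.4 CPM in Chow+T, and STAR was at 225 CPM in WSD+C 4.

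Averaged over both implants, the Western-style diet (n = 11) was compared with chow (n = 8). Oocytes were degenerating in 1 Chow+T, 2 WSD+C and 3 WSD+T libraries, WSD+C 4 and WSD+T 6 among them. The list tests cannot separate diet from oocyte class. Camera called white blood cell markers higher on the diet, lymphocyte by a median log2 fold change of 3.47, macrophage by 3.11, leukocyte by 3.47 and neutrophil by 2.23, each with an adjusted p = 0.555 with an estimated correlation. GZMB (ENSMMUG00000014381), the granzyme of cytotoxic lymphocytes, averaged 0.54 ± 0.35 CPM in Chow+C, 0.27 ± 0.13 in Chow+T, 19.2 ± 41.4 in WSD+C and 2.88 ± 3.42 in WSD+T. CORO1A, a leukocyte actin regulator, averaged 5.68 ± 2.87, 3.36 ± 0.54, 47.4 ± 96.1 and 21.8 ± 30.6 CPM. In WSD+C and in WSD+T the SD of both genes exceeded the mean, and WSD+C 4 alone set their WSD+C means. Of the oxidative phosphorylation genes 21 of 23 had positive values (median 0.15). Among single genes ENSMMUG00000049007 gave 2.85 (SE 0.548), ENSMMUG00000041144 2.42 (SE 0.528), BBS12 -0.88 (SE 0.221), FAM13B -0.79, the transcription termination factor PCF11 -0.83, C5orf41 -0.56, ARID1B -0.40, ENSMMUG00000039519 0.69, ENSMMUG00000038270 3.50 and MSLN 4.44 (2.28 without WSD+C 4), whose SD exceeded its mean in WSD+C and in WSD+T.

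For the diet main effect edgeR called 0 of 15019 genes (smallest adjusted p = 0.701; 1032 at an unadjusted p under 0.05, 775 higher and 257 lower) and limma 0. DESeq2 called 5, ENSMMUG00000049007 (adjusted p = 2.66e-05), ENSMMUG00000041144 (0.00135), GZMB (0.011), MYO1G (0.0257) and FCRL1 (1.47e-13), the last 2 chosen after their values were seen. Without Chow+C 4 edgeR called ENSMMUG00000049007 (3.69, adjusted p = 0.00666). By camera lymphocyte and macrophage markers each had an adjusted p = 5.22e-05, leukocyte 4.84e-04 and neutrophil 0.00197, each lost with an estimated correlation. Adjusted over the list alone, 11 of 13 lymphocyte, 12 of 14 macrophage, 11 of 12 leukocyte and 4 of 8 smooth muscle markers and MSLN passed, against 0 over all genes. These include CD14, CSF1R, LYZ, MRC1, GZMB, NKG7, CD2, CD8A, CORO1A, ITGAL, CD53, CD48, CNN1, ACTA2, RGS5 and TAGLN. The value of ACTA2 was 2.79, and 0.52 without WSD+C 4, and that of TAGLN 2.26 and 0.01. Without WSD+C 4 the lymphocyte (0.88), leukocyte (1.30) and neutrophil (0.51) calls were lost; the macrophage call held in all 19 fits that left out 1 library, with a median of 1.32 without WSD+T 6. Without both of these libraries the macrophage median was 0.01 (adjusted p = 0.95 by camera) and the other 3 were 0.44, 0.15 and 0.28, with no call of the 4 left. With the leukocyte score as a covariate the macrophage (0.15, 0.373), lymphocyte (0.06) and neutrophil calls (0.01) were lost.

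Further lists rose with the diet by camera. Their adjusted p with an estimated correlation was 0.65 for oxidative phosphorylation, 0.429 for prostaglandins and apoptosis and 0.555 for the others. Oxidative phosphorylation (adjusted p = 6.42e-04) lost its call without Chow+C 2 (0.07), as did the prostaglandin pathway (median 0.39, adjusted p = 0.0143; 0.43 without it). Oxidative stress defence (0.26, 0.0101) lost it without Chow+C 2 (0.20), Chow+C 3 (0.23), Chow+T 2 (0.22) or WSD+C 2 (0.18). Erythroid (2.76, 0.0038) and smooth muscle markers (2.11, 0.00715) lost it without WSD+C 4, with medians of -0.16 and 0.22. Endothelium (0.71, 0.0446) kept its call in 8 of 19 fits (0.36 to 0.98; lost without Chow+C 2, 3 or 4, Chow+T 1, 2, 3 or 4, WSD+C 4 or WSD+T 3, 5 or 6), and apoptosis (0.12, 0.0446) in 7 (0.08 to 0.17; lost without any library of Chow+C, Chow+T 2 or 4, WSD+C 2 or 4 or WSD+T 2, 4, 5 or 6). Without both WSD+C 4 and WSD+T 6, and with the leukocyte score as a covariate, erythroid (-0.32 and -0.29), smooth muscle (0.29 and 0.43), endothelium (-0.08 and 0.04) and apoptosis (0.06 and 0.07) lost their calls, while prostaglandins kept theirs (0.24 and 0.28).

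The interaction asks whether testosterone acts differently on the 2 diets. RASSF9 averaged 2.36 ± 0.96 CPM in Chow+C, 8.46 ± 2.68 in Chow+T, 5.25 ± 2.91 in WSD+C and 2.31 ± 1.12 in WSD+T, an interaction of -3.02 on the log2 scale (SE 0.63). LIMS1 averaged 73.1 ± 15.2, 109 ± 3.06, 134 ± 35.0 and 102 ± 11.2 CPM (-0.98, SE 0.253). Other interactions of small p were BST1 (-2.78), NHSL1 (-2.66), the mitochondrial translation gene CLUH (1.34), TOP1MT (1.48), SH2D7 (3.73, and 2.20 without Chow+C 2), CKB (7.47, at means under 1 CPM in each group), ENSMMUG00000047461 (-4.49) and ENSMMUG00000039486 (-3.58). FSHR gave -2.49 (CI -4.72 to -0.26), and -0.54 without WSD+C 4. By edgeR 0 of 15019 genes passed (smallest adjusted p = 0.933; 679 at an unadjusted p under 0.05, 393 higher and 286 lower), by limma 0 and by DESeq2 3, RASSF9 (adjusted p = 0.00796), CKB (0.0352) and FCRL1 (3.52e-08). Camera called cell cycle (median -0.66, adjusted p = 0.00159), cholesterol synthesis and uptake (0.33, 0.0087) and neutrophil markers (0.92, 0.0281), each with an adjusted p = 0.971 with an estimated correlation. Cell cycle lost its call without Chow+C 2 (-0.56) and was -1.42 without Chow+C 4 and -0.43 without Chow+T 2. Cholesterol synthesis lost it without Chow+C 1 (0.16), Chow+C 3 (0.13), Chow+T 2 (0.08) or WSD+C 4 (0.07) and was 0.66 without Chow+T 4. Neutrophil markers lost it without Chow+C 1 or 4, Chow+T 1 or WSD+C 1, 2 or 3 (0.50 to 0.69) and were 4.66 without WSD+C 4. Cholesterol synthesis was 1.09 and neutrophil markers 1.73, both called, with the leukocyte score as a covariate. The interaction has the least power, with a median SE of 0.507 against 0.254 for the main effects.

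Libraries with a degenerating oocyte (n = 6; 0 in Chow+C, 1 in Chow+T, 2 in WSD+C and 3 in WSD+T) were compared with those whose oocyte had resumed meiosis (MI or MII, n = 12). Camera called white blood cell markers higher with degeneration, calls lost with an estimated correlation. Medians were 4.46 for leukocyte, 3.86 for macrophage, 3.75 for lymphocyte and 2.94 for neutrophil markers. CORO1A averaged 57.2 ± 84.8 CPM (n = 6) against 4.89 ± 2.34 CPM with MI (n = 8) and 4.49 ± 1.56 CPM with MII (n = 4), and the integrin gene ITGAL 39.4 ± 57.8 against 0.70 ± 0.61 and 1.93 ± 1.30 CPM. Both were highest in WSD+C 4 (219 and 136 CPM) and WSD+T 6 (82.2 and 85.6 CPM). KRT18 (ENSMMUG00000031911), an epithelial keratin, averaged 51.3 ± 57.9 CPM against 11.7 ± 16.3 with MI and 2.62 ± 0.87 with MII (log2 fold change 3.78, SE 0.838), and IRF4, a lymphoid transcription factor, gave 3.59 (SE 0.801). FAM43A (1.91), the macrophage growth factor gene IL34 (0.95), the RNA-binding protein gene IGF2BP2 (1.06), OPRL1 (3.15), IFITM10 (2.63), COL22A1 (-3.16), ENSMMUG00000014786 (5.54) and ENSMMUG00000019688 (-3.78) were the others of smallest p. Of the panel, CYP19A1 gave -1.01 (CI -2.35 to 0.33), AREG 2.00 (CI -0.13 to 4.12) and ESR2 2.22 (CI 0.35 to 4.08; 1.26 without WSD+T 3).

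By edgeR with treatment as a term 0 of 14976 genes passed for degenerating oocytes (smallest adjusted p = 0.493), and by limma 0. By edgeR 1477 were at an unadjusted p under 0.05, 1105 higher and 372 lower, where chance gives 749. Leaving out 1 library, that number ranged from 778 (without WSD+C 4) to 2278 (without WSD+T 4). It was 513 without both WSD+C 4 and WSD+T 6. DESeq2 called 565 (532 higher, 33 lower), among them KRT18 (adjusted p = 4.35e-04), CD48 (4.53e-04), IRF4 (6.62e-04), ITGAL (6.62e-04), COL22A1 (0.00159), GZMB (0.00244) and CORO1A (0.0027). Without the treatment term edgeR called 586, with 582 higher, and 435 genes passed in both in the same direction. Those 586 hold 11 of 12 leukocyte, 12 of 14 macrophage, 9 of 13 lymphocyte, 3 of 11 neutrophil and 4 of 9 erythroid markers and 0 of 11 granulosa markers. They also hold 2 of 8 endothelium, 2 of 8 smooth muscle, 1 of 10 theca and stroma and 1 of 6 surface epithelium markers. Platelet (0 of 6) and oocyte markers (0 of 9) are not among them. GZMB (5.26), ITGAL (5.08), CD48 (4.97), CORO1A (3.61) and IRF4 (3.21) had the smallest adjusted p there, 0.0318, while SEPSECS (-0.70), TRABD2A (-1.47) and TMEM52 (-1.18), chosen after their values were seen, were lower. With the leukocyte score as a covariate, or without WSD+C 4 and WSD+T 6, 0 of these remained past the threshold. With treatment and the covariate together edgeR called 1 gene, BMP15. Among the degenerating libraries this oocyte gene was near 0 in all but WSD+C 4. The call therefore cannot be separated from the oocyte RNA of that library.

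By camera the degenerating class had adjusted p of 1.2e-06 for neutrophil, 1.7e-06 for lymphocyte and 8.14e-06 for leukocyte and macrophage markers, each with an adjusted p = 0.565 with an estimated correlation. All 4 calls held in the 18 fits that left out 1 library. Without WSD+C 4 the medians were 2.87 for leukocyte, 2.08 for lymphocyte and 1.83 for neutrophil markers, and without WSD+T 6 the macrophage median was 1.86. Without both libraries the macrophage call was lost (0.52, adjusted p = 0.163 by camera), and the medians were 1.10 for leukocyte, 1.70 for lymphocyte and 1.72 for neutrophil markers. With the leukocyte score as a covariate the neutrophil call was kept (0.78), and those of macrophage (-0.44) and lymphocyte markers (0.29) were lost. Adjusted over the list alone, 8 of 13 lymphocyte markers (CD247, CD3G, CD8A and GZMB among them), 11 of 12 leukocyte markers (PTPN6, CORO1A, ITGAL and CD48 among them), ITGA2B of the platelet list and CLDN4 and MSLN of surface epithelium passed, against 0 over all genes. Cell cycle genes fell (median -0.43, 7 of 25 positive, adjusted p = 6.82e-04; adjusted p = 0.617 with an estimated correlation) in all 18 fits, from -0.84 (without WSD+T 1) to -0.26 (without WSD+T 3), and were -1 without both WSD+C 4 and WSD+T 6 and -0.95 with the covariate. Oxidative phosphorylation (-0.23, 5.66e-04) and endoplasmic reticulum stress genes (-0.35, 0.00309) fell, but lost the call without WSD+C 4 (-0.11 and -0.16); their adjusted p was 0.618 and 0.565 with an estimated correlation. Erythroid (2.85, 0.00598) and platelet markers (1.46, 0.011) lost it without WSD+C 4 (0.78 and 0.81) or WSD+T 1 (2.24 and 1.32), and interferon response (0.89, 0.011) without WSD+C 4 (0.55), WSD+T 1 (0.56) or WSD+T 6 (0.57). Without Chow+T 1 the erythroid median was 4.49 and the interferon median 1.35. With the covariate these 5 calls were lost (-0.12, -0.15, -0.07 and 0.17 for the first 4), interferon response turning to -0.44 (adjusted p = 0.033 by camera), and without both WSD+C 4 and WSD+T 6 they were lost as well. For erythroid, platelet and interferon genes adjusted p was 0.617, 0.565 and 0.618 with an estimated correlation. By exact permutation of list scores the leukocyte score was 4.31 ± 2.79 against 1.75 ± 1.28 (adjusted p = 0.0984) and the cytokine and NF-kB score 0.61 higher (adjusted p = 0.0824, the smallest of 34). Permuted within treatment groups, the adjusted p was 0.668 and 0.267, the latter again the smallest. With 600 such arrangements a single list could not pass after adjustment.

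MII oocytes (n = 4) were compared with MI oocytes (n = 8) to ask what differs in the granulosa cells when the oocyte has completed the first meiotic division. Chow+T has no MI library and WSD+C no MII library. With treatment as a term the classes therefore meet within a group only in Chow+C (3 MI; MII Chow+C 4) and WSD+T (2 MI; MII WSD+T 1), and the other libraries count through the degenerating class. Camera called sterol and steroid synthesis lower with MII, calls lost with an estimated correlation. All 23 genes of cholesterol synthesis and uptake had negative log2 fold changes (median -1.02), as did 16 of 17 of steroid synthesis (median -0.41). STAR, which carries cholesterol into the mitochondrion for steroid synthesis, averaged 3891 ± 1447 CPM with MI and 1699 ± 1222 CPM with MII (log2 fold change -1.51, CI -3.24 to 0.22), and HSD3B2, which makes progesterone, 655 ± 364 and 225 ± 149 CPM (-1.74, CI -4.33 to 0.86). Fatty acid synthesis and lipid storage (-0.54, 3 of 25 positive) and glycolysis genes (-0.44, 4 of 22) were also called lower, and cell cycle genes (median 1.40, 21 of 25 positive) and interferon response genes (1.27, 20 of 21) higher. These calls were lost with an estimated correlation. Single genes of small p were C9orf129 (4.17 ± 1.20 and 1.39 ± 0.97 CPM; -2.74, SE 0.435), the mitotic kinesin KIF20B (14.3 ± 7.62 and 34.3 ± 11.8 CPM; 1.61, SE 0.316), the adhesion molecule ALCAM (26.2 ± 10.2 and 108 ± 74.2 CPM; 2.59, SE 0.564), TEX14 (2.07), POLR1B (-0.87) and ENSMMUG00000000050 (3.28, and 2.16 without WSD+T 1).

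Oocyte genes were higher with MII (median 8.62, 9 of 9 positive, camera adjusted p = 2.73e-12; adjusted p = 0.253 with an estimated correlation), a fitted value that depends on the prior count because most libraries are near 0. ZP2, a protein of the zona pellucida, was at 3.08 CPM in Chow+C 4 and 2.06 CPM in WSD+T 1, both MII, at 2.70 CPM in WSD+C 3, an MI library, and at 0 in Chow+T 2 and Chow+T 3, both MII. NLRP5, PADI6, BMP15, NLRP7 and GLP2R had fitted values of 8.10 to 8.79, and 7 of 9 oocyte markers passed when adjusted over the list alone, against 0 over all genes. The oocyte list median was 4.49 without WSD+T 1, 5.20 without Chow+T 2 and 5.39 without Chow+T 3, the call holding in all 16 fits that could be made. It could not be tested without WSD+C 3 or WSD+C 4. The oocyte score was -1.74 ± 2.62 with MII and -3.26 ± 1.71 with MI (exact permutation test, two-sided, adjusted p = 0.763).

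By edgeR 0 of 14976 genes passed between MII and MI (smallest adjusted p = 0.227, C9orf129; 586 at an unadjusted p under 0.05, 331 higher and 255 lower), and by limma 0 (1881 at an unadjusted p under 0.05). DESeq2 called 6, among them C9orf129 (adjusted p = 9.21e-08), ALCAM (0.0131), KIF20B (0.015) and TEX14 (0.0448). Camera's adjusted p was 6.21e-18 for cholesterol synthesis, 5.55e-13 for cell cycle and 2.79e-12 for interferon response, each with an adjusted p = 0.253 with an estimated correlation. It was 5.17e-05 for glycolysis, 6.12e-05 for steroid synthesis and 9.94e-05 for fatty acid synthesis, with 0.284, 0.284 and 0.259 with an estimated correlation. These 6 calls held in all 18 fits that left out 1 library. Their medians ranged from -1.15 to -0.80, 1.04 to 1.83, 0.92 to 1.90 (without WSD+T 1), -0.58 to -0.34, -0.59 to -0.31 and -0.66 to -0.39. With the leukocyte score as a covariate steroid synthesis lost its call (-0.21, adjusted p = 0.188 by camera), and the other medians were -0.63 for cholesterol synthesis, 0.57 for cell cycle, 0.44 for interferon response, -0.35 for glycolysis and -0.28 for fatty acid synthesis. White blood cell markers rose with MII too, lymphocyte by 2.25 (adjusted p = 4.89e-07), leukocyte by 2.13 (1.44e-05) and neutrophil by 1.86 (1.78e-05), with adjusted p of 0.357, 0.357 and 0.289 with an estimated correlation. Without Chow+T 1 these medians were 1.12, 1.06 and 0.98, and they were 3.38 without Chow+C 1, 4.65 without Chow+C 4 and 3.37 without WSD+T 1. With the covariate the lymphocyte (0.38) and neutrophil calls (0.58) were lost.

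Camera called 4 further lists between MII and MI, with adjusted p of 0.473, 0.583, 0.408 and 0.555 with an estimated correlation in the order below. Erythroid markers rose (2.06, camera adjusted p = 9.95e-04; 0.77 without Chow+T 1, 4.25 without Chow+C 1, and 0.41 with the call lost with the covariate), as did macrophage markers (1.08, 0.00143; 0.10 and the call lost without Chow+T 1, 4.17 without WSD+T 1, and -1.08 with an adjusted p = 0.032 with the covariate). Granulosa markers fell (-0.34, 0.0353), a call lost without WSD+T 1, Chow+C 3, WSD+C 1, WSD+C 4 or Chow+T 2 (-0.52 to -0.22), with -0.81 without Chow+C 4 and also lost with the covariate (-0.21). Oxidative stress defence fell (-0.27, 0.048) in 9 of 18 fits (-0.36 to -0.17), the call being lost without Chow+C 1, Chow+T 1 or 2, WSD+C 1, 2, 4 or 5 or WSD+T 1 or 6. Exact permutation tests of list scores, not within treatment groups, gave a smallest adjusted p of 0.103, for steroid synthesis (6.66 ± 0.46 with MII, 7.19 ± 0.15 with MI) and cholesterol synthesis (7.15 ± 0.60 and 7.88 ± 0.20). With 495 arrangements a single list could not pass after adjustment.

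No camera call held with an estimated correlation in any of the 10 comparisons, fry called 0 lists (smallest adjusted p = 0.236) and no list score passed its exact permutation test after adjustment in the 9 comparisons where it was run (not the interaction). For no called list did the median, the mean and the test differ in sign with all libraries in. Heat shock, cytokines and NF-kB, TGF-beta and BMP signalling, theca and stroma, extracellular matrix and proteases, surface epithelium, androgen response and angiogenesis were called in none. Their smallest adjusted p by camera was 0.0501 for heat shock (both exposures, median 0.20), 0.0564 for cytokines and NF-kB (diet, 0.30), 0.111 for TGF-beta and BMP (interaction, -0.20), 0.133 for theca and stroma (diet, 0.23), 0.144 for extracellular matrix (testosterone, 0.18), 0.16 for surface epithelium (degenerating, 0.78) and 0.162 for androgen response (testosterone, 0.11) and angiogenesis (testosterone, 0.16).

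Mitochondrially encoded genes differed between single libraries. In CPM of gene counts, without TMM scaling, MT-CO3 was at 4.33 to 11.9 CPM in Chow+C 1, Chow+C 3, Chow+T 2 and WSD+T 2 and at 2190 to 27900 CPM in the other 15 libraries, while MT-CYB was at 3980 to 10000 CPM in those 4 and 5600 to 40400 CPM in the others. In Chow+T 4, which keeps MT-CO3, the log2 ratio of MT-ATP6 to MT-ATP8 was -8.4, against 0.59 or more in the 14 libraries that keep both. None of these genes is in the oxidative phosphorylation list.

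**Figure D4:**
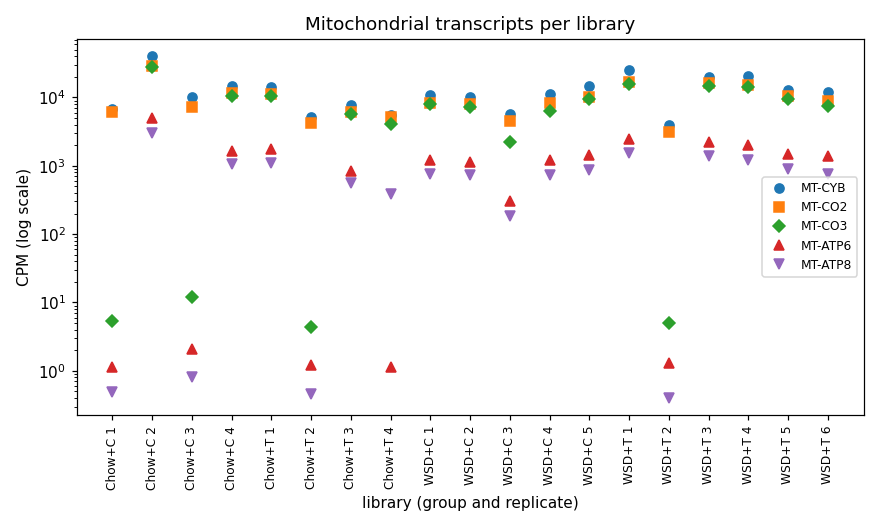
CPM of gene counts, without TMM scaling (y axis, log scale), of MT-CYB, MT-CO2, MT-CO3, MT-ATP6 and MT-ATP8 (points by colour and shape) in each of the 19 libraries (x axis). MT-CO3 was at 4.33 to 11.9 CPM in Chow+C 1, Chow+C 3, Chow+T 2 and WSD+T 2 and at 2190 CPM or more in the others.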

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

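The 8 tests of the 3 patterns weighed below were written only after the result was seen; the regroupings of libraries were planned. In 212 groups of values, 29 held a library far from the rest of its group, where chance gives about 1 in 20 groups, or 10.6.

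Of these 29, WSD+C 4 accounted for 18. Its 10 most abundant genes took 24.6% of gene counts (6.39% to 8.49% in the rest of WSD+C). Scores below the rest of the group were those of steroid synthesis (4.66; others 6.95 to 7.29), cholesterol synthesis and uptake (4.8; 7.53 to 8.03), ovulatory response (3.62; 6.5 to 6.9), glycolysis (4.65; 5.42 to 5.73), insulin and IGF signalling (5.87; 6.31 to 6.49) and the prostaglandin pathway (3.22; 3.77 to 3.92). Scores above it were those of interferon response (4.26; 1.01 to 1.76), endothelium (2.71; -0.598 to 0.316) and smooth muscle (5.43; 0.0903 to 1.47). In CPM, AREG was at 4.27 (242 to 828), INHA at 231 (4760 to 7200), LHCGR at 0.425 (13.5 to 46.4), STAR at 225 (2070 to 4410), SCARB1 at 56.8 (2840 to 4930), HSD3B2 at 4.22 (333 to 901), PTGS2 at 35.8 (1130 to 2350) and FSHR at 81 (3.81 to 6.74).

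The other 11 lay in 8 libraries. In Chow+C 1 the preovulatory granulosa score was 5.36 (others 5.8 to 5.84) and the endothelium score 1.08 (-0.116 to 0.0612). In Chow+C 2 the fatty acid oxidation score was 5.6 (5.15 to 5.19). In Chow+T 2 the macrophage score was 3.46 (-0.79 to -0.148) and the fatty acid synthesis score 5.18 (5.63 to 5.72). Chow+T 1 had FSHR at 2.02 CPM (7.38 to 8.38), and Chow+T 4 an angiogenesis score of 2.65 (3.47 to 3.54). WSD+T 6 had an efflux and storage score of 7.46 (6.25 to 6.39) and LHCGR at 1.96 CPM (11.7 to 25.2). WSD+T 3 had a cell cycle score of 2.45 (3.65 to 4.29), and WSD+T 1 an oocyte score of 0.423 (-4.25 to -3.83).

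The effect of testosterone differed between the diets by camera on the interaction term for cell cycle (median -0.66, adjusted p = 0.00159), cholesterol synthesis and uptake (0.329, 0.0087) and neutrophil markers (0.918, 0.0281), each with an adjusted p = 0.971 with an estimated correlation. Among reads outside genes, the multimapping share was 18.3% in WSD+C 4, above the highest of Chow+C (13.5%). The unmapped share was above the highest of Chow+C (1.91%) in WSD+C 1 (3.92%), WSD+C 4 (2.74%), WSD+T 6 (2.57%), WSD+T 2 (2.09%), WSD+C 5 (1.97%), Chow+T 4 (1.96%) and WSD+T 5 (1.94%).

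The first pattern weighed is the leukocyte score, which was 2.56 higher with a degenerating oocyte (SE 0.944, n = 6 and 12). If blood carried into the aspirate were the source, the difference should vanish once the erythroid score is held constant. It was then 1.15 (SE 0.77), within 2 SE of 0, and 1.81 (SE 1.16) for macrophage markers, so white cells of blood and of the follicle cannot be told apart here, because the SE is too wide to separate no difference from most of the original one. A lower share of granulosa RNA would raise markers of other cell types as much. With the treatment group as a term the leukocyte difference exceeded that of endothelium, the closest type, by 1.39 (SE 0.737), and the endothelium score itself was 1.16 higher (SE 0.484). For theca and stroma, surface epithelium and smooth muscle the excess was 2.06 (SE 0.847), 1.9 (SE 1.09) and 1.67 (SE 0.811). Without the treatment term each excess passed 2 SE. It was 1.51 (SE 0.645) for endothelium and 2.04 (SE 0.728) for theca and stroma. For surface epithelium it was 1.92 (SE 0.937) and for smooth muscle 1.71 (SE 0.729). With the term not all exceed 2 SE, so a lower share of granulosa RNA cannot be told apart from a rise of leukocytes alone. Endothelium and smooth muscle were added to the comparison after the first 2 types had been seen. Without WSD+C 4 and WSD+T 6, which carry the difference, it was 0.977 (SE 0.802) and its excess over theca, stroma and surface epithelium together 0.723 (SE 0.728), so in the other 4 libraries that share cannot be told apart from no difference. Leukocytes in a follicle whose oocyte degenerates remain a hypothesis that the oocyte class, a label of the design, allows but no test here isolates.

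The second pattern is the near absence of MT-CO3, MT-ATP6, MT-ATP8 and COX1 in Chow+C 1, Chow+C 3, Chow+T 2 and WSD+T 2. COX1 was at 1.9 to 4.15 CPM there, MT-CO2 at 3150 to 7320 (others 4480 to 28600) and ND3 at 368 to 948 (752 to 4380). Lower mitochondrial transcription alone would lower MT-CO2 as much. The log2 ratio of MT-CO3 to MT-CO2, set by the choice of libraries, was at most -9.26 there and at least -1.03 in the other 15. This excludes lower transcription only as sole cause. A mitochondrial variant against the reference should lower MT-ATP6 against MT-ATP8, with which it shares a transcript. Their log2 ratio was 1.21 or more in the 4 libraries and 0.59 to 0.855 in the 14 that keep both, but at 17 to 74 counts in the 4 it rests on few reads, and a variant that removes both genes cannot be told apart from another loss. Reads moved to the multimapping class cannot be told apart from their loss. The shares of the 4 libraries (at most 8.49%) lie below the median of the others (10%) but inside their range (7.03% to 18.3%). The bound first written was met and was made stricter after its value was seen. The no-feature share was 21.5% to 28.9% in the 4 libraries (median 25%) and 18.3% to 33.5% in the other 15 (median 20.6%). Reads moved to that class were not tested. No other biological explanation was tested.

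The third pattern is oocyte RNA in Chow+C 4, WSD+C 3 and WSD+T 1. Carry-over from WSD+C 4, which holds the most, would bring its erythroid RNA in the same share, but the ratio of erythroid to oocyte share was at most 0.126 and carry-over is excluded. With oocyte RNA in the aspirate most oocyte markers should be present together. At least 8 of 11 had 10 counts or more in each of the 3, against at most 3 in the 15 others besides WSD+C 4. The 3 libraries were singled out by these same transcripts, so this count restates the choice and cannot test the source. No biological explanation was tested.

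Regrouping the same libraries 100 times, the real grouping included, gave as many genes past the threshold in 100 of 100 for all 10 comparisons, since the real count was 0. The highest counts in other groupings were 852 for testosterone on chow, 214 for diet without testosterone, 1457 for both exposures, 1 for testosterone on the Western-style diet, 1013 for diet under testosterone, 370 for the testosterone main effect, 501 for the diet main effect, 425 for the interaction, 1145 for degenerating oocytes and 600 for MII against MI. Counts at an unadjusted p under 0.05 as large as the real ones (1079, 763, 1014, 579, 747, 948, 1032, 679, 1477 and 586, in the same order) arose in 39, 60, 46, 81, 68, 44, 49, 75, 15 and 56 groupings, with highest counts of 4078, 3368, 4863, 3304, 3178, 3758, 3274, 3419, 4203 and 4371. Without the treatment term the 586 genes called for degenerating oocytes were matched in 3 of 100 groupings (highest other 953).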

How the results depend on the processing

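Fits without the 2 libraries of highest leukocyte score (WSD+C 4, WSD+T 6), or these and Chow+C 2, were chosen after the data were seen. So were the exact permutation tests of list scores and the list tests with the leukocyte covariate or without 1 library. List tests were not repeated with RLE factors, without the low-count filter or with the oocyte class as a covariate. Counts of genes past the threshold stayed at 0 in all 10 comparisons with RLE factors, no low-count filter, limma and without those 2 libraries (or those and Chow+C 2), in the 8 treatment comparisons with the oocyte class as a covariate, and in the 5 pairwise ones with only the 2 groups compared; the genes below depend on the tool or the design. DESeq2 called 5 for testosterone on chow, 0 for diet without testosterone, 3 for both exposures, 0 for testosterone on the Western-style diet, 4 for diet under testosterone, 3 for the testosterone main effect, 5 for the diet main effect, 3 for the interaction, 565 for degenerating oocytes and 6 for MII against MI. The MI and MII libraries alone (only 2 of Chow+T, both MII) gave 4 for testosterone on chow and 1 for diet under testosterone. For degenerating oocytes the leukocyte covariate gave 1, and no treatment term 586. Leaving out 1 library gave 0 genes in each comparison except the diet main effect (0 to 1). The cause was not tested.

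Lists called by camera's preset test (2, 2, 9, 12, 9, 12, 11, 3, 10 and 14, in the order above) fell to 0 in every comparison with an estimated correlation and with fry, and with exact permutation of list scores in the 9 where it was run. With few arrangements, no single list could pass that permutation test in the 5 pairwise comparisons or in MII against MI. The leukocyte covariate moved the number of called lists to 4 for testosterone on chow, 1 for diet without testosterone, 14 for both exposures, 7 for the diet main effect, 5 for degenerating oocytes and 7 for MII against MI. In these counts the leukocyte list, adjusted for its own score, is fixed near 0, so its loss says nothing. Macrophage, lymphocyte and neutrophil markers also belong to white blood cells, so their loss with that covariate tells little in any comparison. Without the 2 libraries it moved to 4 for testosterone on chow, 10 for diet without testosterone, 5 for the testosterone main effect, 10 for the interaction and 6 for degenerating oocytes. Leaving out 1 library at a time gave 0 to 5, 2 to 10, 8 to 13, 9 to 16, 6 to 13, 5 to 13, 7 to 15, 1 to 11, 6 to 15 and 11 to 17 called lists in that order. The cause was not tested.

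Medians of 14 called lists took the opposite sign in 26 values (that list with its own covariate left out), 4 of them past the threshold in the opposite direction. Erythroid markers for testosterone on the Western-style diet (-4.40) became 1.45 without WSD+C 4 (adjusted p = 0.00161 by camera) and 1.14 without the 2 libraries (0.00934). Leaving out 1 library at a time, they ranged from -4.75 to 1.45. With the leukocyte covariate, interferon response with degenerating oocytes became -0.44 (0.033) and macrophage markers with MII -1.08 (0.032). The other 22 were not called in the opposite direction. Among them, for testosterone on the Western-style diet, the neutrophil median was -0.42 to -0.07 in 6 fits without 1 library, and the macrophage median -1.29 without WSD+T 6. The cause was not tested. Of all list values, these 26 included, 1475 kept the test's direction and their side of the threshold, 396 were weaker and 22 moved. No gene passed in a main fit, so the 7046 named-gene values counted as same (362 moved, 56 stronger) say little on size.

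No paired analysis was possible because replicates are separate animals numbered in sample order. Depth of 28832132 counts or more limits genes near 0, such as those of the oocyte, whose fitted folds depend on the prior count. Exact permutation was not run for the interaction, and the oocyte list had no value in fits that left too few of its members.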

Other observations

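Chow+T 4, the only library with a GV oocyte, entered no comparison of oocyte classes. Its granulosa score was 7.66, its leukocyte score 1.57 and its oocyte score -2.52, and 3 of 11 oocyte markers had 10 counts or more. STAR was at 4259 CPM, SDC4 at 34.25 CPM and FHL2 at 102 CPM in that library.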
